A study of Mus musculus with 4 samples.

How the data were processed

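RNA of sorted mouse bone marrow cells was measured on 4 Affymetrix whole-genome mouse expression arrays, 2 for long-term haematopoietic stem cells (LT-HSC) and 2 for short-term haematopoietic stem cells (ST-HSC). The groups and the replicate numbers came from the sample titles, and the gates named in the labels (lineage-negative, cKit+, Sca1+, CD135-, with CD34- for LT-HSC and CD34+ for ST-HSC) fit those titles. The tissue entry of both ST-HSC samples reads LT-HSC beside the CD34+ gate, and the title was used. Per the labels' protocols, RNA was purified with Trizol, amplified in 2 rounds and labelled with biotin in an Affymetrix kit. The deposited values are intensity values on a linear scale, 1 per probe set and array. The software that summarised the probes, and any scaling between arrays, are not given in the sources used here. The table held 45101 probe sets, of which 64 were Affymetrix controls that were left out of all tests.

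The medians of the 4 arrays spanned 0.33 on the log2(intensity + 16) scale and their upper quartiles 0.35, above the limit of 0.2 set for using the values as they were, so the arrays were quantile normalized. The pseudocount of 16 understates the fold of dim probe sets, and every fold below is on that scale. Probe sets whose mean over the 4 arrays was not above the 40th percentile were left out, which left 27022. LT-HSC and ST-HSC were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and p-values were adjusted by Benjamini-Hochberg over all tested probe sets, with a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior of 4.83 degrees of freedom. Differences are LT-HSC minus ST-HSC with the moderated standard error (SE). Array intensities carry no counts, so the number of arrays limits the precision. With 2 arrays against 2, the smallest two-sided p of an exact permutation test is 0.33, so single genes were tested by limma alone.

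Probe sets were named through the platform annotation that was supplied, which gave 1 gene symbol to 34958 probe sets and several to 932, while 9160 were unnamed here. Of the named probe sets, 34754 had an Entrez identifier in a RefSeq table of assembly GRCm38.p6, and 0 symbols needed an update. A gene was represented by its brightest probe set with 1 symbol, which gave 12832 genes. Of the genes called, 10 had another probe set called in the opposite direction. Genes without a named probe set, among them the Sca1 gene, were not analysed here.

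The design, the lists and the alternatives were fixed before the data were examined: 33 gene lists of stem cell, lineage, cell cycle and pathway genes and of markers of other marrow cells. Each list was tested with camera in limma at a preset correlation between genes of 0.01, on 1 probe set per gene, and beside it with camera at an estimated correlation and with fry, which asks whether a list moves on balance one way. All list p-values were adjusted over the 33 lists. Counts of members are given over all probe sets tested and, where so worded, adjusted over the list alone. The named genes are, in each direction, the 15 of largest fold among those past the threshold with both arrays of one group above both of the other. Added to them were the sort markers, up to 4 members of smallest p per list, and members needed as exceptions. The following genes lie outside this rule and were chosen after their values were seen: Bcl2l11, Btg2, Camp, Cbx2, Cd27, Cd68, Cdk4, Eif2s3y, Fos, Hdac2, Hlf, Ighm, Igk, Jchain, Lmo2, Ly6d, Mecom, Ngp, Pkm, Procr, Sdc1, Xbp1, Xist and the members of the later lists. Of lists made after the data were seen (plasma cells, innate lymphoid and T-lineage cells, genes shared by stem and progenitor cells), results stand in the closing section.

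The procedure was tested on simulated data for this comparison, on 27022 probe sets. With 200 changed probe sets, 100 at 2-fold and 100 at 4-fold, the recovered share was 0% at both sizes, although 97% and 100% had the right direction. With 2702 probe sets changed 4-fold, 70.1% were recovered and 4.05% of the calls were false. A simulated list of 30 genes shifted by 1 on the log2 scale had an adjusted p of 6.73e-33 in camera, 0.169 with an estimated correlation and 0.0146 in fry. The simulated noise was independent between probe sets and equally wide in both groups. The real pairs differed in spread (SD between arrays 0.49 in LT-HSC and 0.70 in ST-HSC), so these shares and p-values may not carry over to the real calls. The alternatives were other normalizations, filters, pseudocounts, spread models, thresholds and rules for a gene's probe set, and each array left out in turn. With an array left out, the filter on dim probe sets was applied again to the arrays kept. A list's tested members, and so its median, can therefore differ from the main comparison. Values with no normalization between arrays were added after the data were seen. Labelling spikes and the 3′ and 5′ probe sets of beta-actin and Gapdh were read from the deposited intensities as signs of array and RNA quality.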

Results

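Gene expression was compared between LT-HSC, the marrow fraction defined by lasting reconstitution of the blood system, and ST-HSC, its CD34+ neighbour with shorter reconstitution. The mice were controls without the inducible Mx-Cre transgene. All had received 7 injections of poly(I:C), a synthetic double-stranded RNA that induces interferon. LT-HSC replicates 1 and 2 and ST-HSC replicate 2 came from mice of 7.5 weeks, taken 4 weeks after the last injection, and ST-HSC replicate 3 from mice of 8.5 weeks, taken 3 weeks after it. Median intensities of the arrays were 19.1 and 28.3 for LT-HSC and 26.9 and 25.9 for ST-HSC. By these ages the ST-HSC replicates came from different mice. Nothing in the labels says whether the LT-HSC replicates came from separate animals or pools, so the spread of that pair may be technical only. The comparison asks which genes differ between these neighbouring stages of normal haematopoiesis.

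Of 9 B-cell markers 4 were higher in LT-HSC and 0 lower, and in ST-HSC 31 of 41 genes of DNA replication and 40 of 49 of G2 and mitosis were higher. Cd34, the surface marker that separated the gates, was 27.4-fold higher in ST-HSC, with log2 means of 10.03 ± 0.26 (SD, n = 2) against 5.26 ± 0.09 (SD, n = 2) in LT-HSC (difference -4.78, SE 0.31, adjusted p = 0.000473). Kit, the stem cell factor receptor, was 2.03-fold higher in ST-HSC (difference -1.02, SE 0.26, adjusted p = 0.0497). That call was lost without LT-HSC replicate 1 (adjusted p = 0.38), without LT-HSC replicate 2 (adjusted p = 0.32) and under 8 of the other settings, and a second, dim probe set of Kit differed by 0.05. Flt3, which encodes CD135 and against which both gates selected, lay at -1.37 (SE 0.38) and did not pass (adjusted p = 0.0633). It passed without ST-HSC replicate 3 (-1.74, adjusted p = 0.00329), with the arrays centred on their medians (-1.35, adjusted p = 0.041) and with probe sets averaged per gene (adjusted p = 0.0331). The sort markers as a list were lower in LT-HSC (median -1.37, 3 fell adjusted over the list alone, camera adjusted p = 0.0117, adjusted p = 0.469 with an estimated correlation). In limma, 3293 of 27022 probe sets passed, 1814 higher in LT-HSC and 1479 higher in ST-HSC, and 8210 had an unadjusted p under 0.05. They stood for 1837 of 12832 genes, 1016 higher in LT-HSC and 821 higher in ST-HSC. The array pairs set these counts: without LT-HSC replicate 1 or 2, 249 or 253 genes passed, and without ST-HSC replicate 2 or 3, 4801 or 3532. Of the 15 genes of largest fold in ST-HSC, 8 and 9 passed without LT-HSC replicate 1 and 2, and of the 15 in LT-HSC, 14 passed without either. Of the 12832 genes, 64.3% had both arrays of one group above both of the other, where chance gives 33.3%.

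The genes of largest fold in LT-HSC included immunoglobulin heavy chains and a plasma cell receptor. Ighg3 was 217-fold higher (log2 difference 7.76, SE 0.30, adjusted p = 0.000149) and Igha 114-fold higher (6.84, SE 0.99, adjusted p = 0.00919), with Igha at 13719 and 14222 in LT-HSC against 19.5 and 399 in ST-HSC. Tnfrsf17, the receptor BCMA of plasma cells, was 107-fold higher (6.74, SE 0.33, adjusted p = 0.000204). The other genes among the 15 largest were Trpd52l3, Psca, Mak, Syngr3, Ldah, 4930545H06Rik, Zfp575, Gsta2, Bves, Aplp2, Ccdc28a and Pard3, with log2 differences from 6.70 for Pard3 to 8.08 for Trpd52l3. Psca, a surface antigen of epithelial cells, read 4207 and 4118 in LT-HSC and 0.0391 and 0.0416 in ST-HSC, so its 232-fold difference rests on the pseudocount. Of these 15 genes 8 had 1 tested probe set, and of the 7 with more, 4 (Mak, Ldah, Ccdc28a and Pard3) had no second probe set that passed. The lowest of the further probe sets of Aplp2, Ldah and Ccdc28a had log2 differences of -0.38, -0.65 and -0.90, none of which passed. Chosen after their values were seen, the plasma cell genes Sdc1 (syndecan-1, CD138), Jchain (the joining chain of IgA and IgM) and Xbp1 (a factor of secretory cells) were 44.0-, 9.97- and 13.9-fold higher in LT-HSC.

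**Figure D1:**
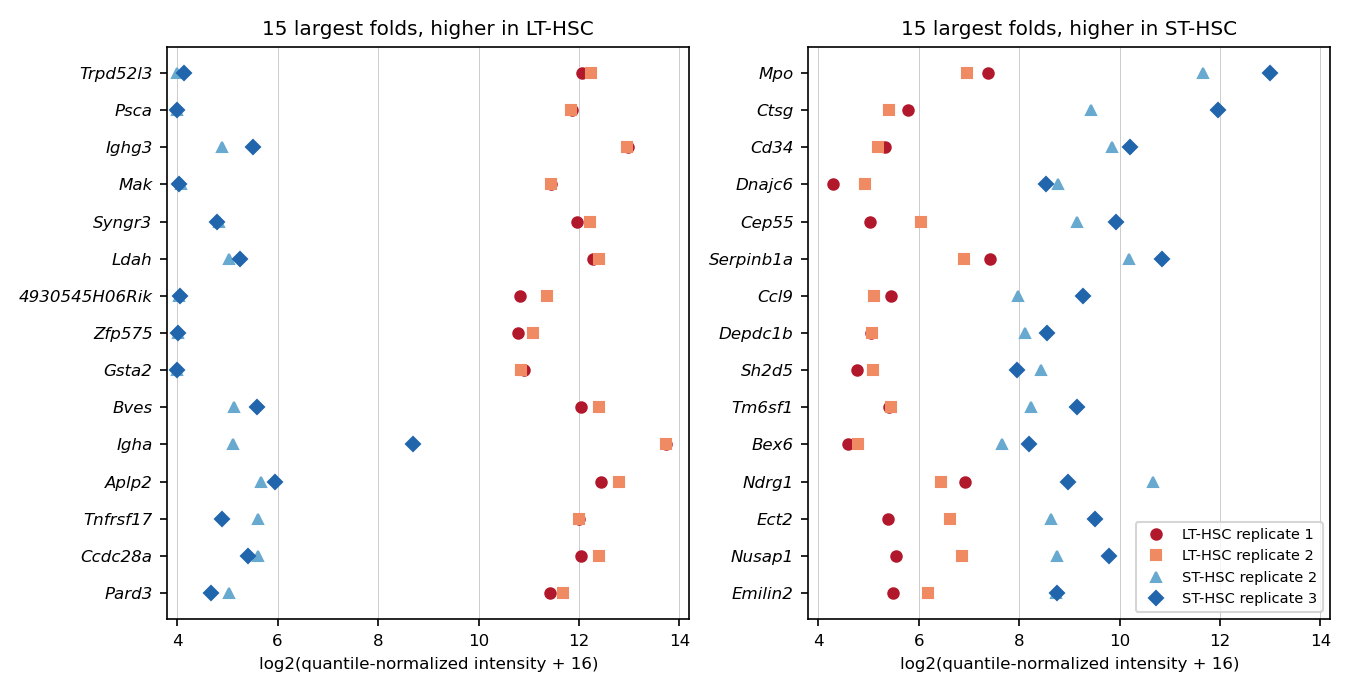
Log2(quantile-normalized intensity + 16) on each of the 4 arrays for the 15 genes of largest fold in each direction. Each symbol is 1 array. In the left panel both LT-HSC arrays lie above both ST-HSC arrays for every gene, with Igha the widest apart within ST-HSC, and in the right panel Mpo, Ctsg and Cd34 lead.

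Of 9 tested markers of B cells, which a lineage gate is meant to remove, 4 were higher in LT-HSC, 0 were lower and 5 did not pass (4 and 0 adjusted over the list alone). These were Ms4a1 (CD20), Cd79a and Cd79b (the signalling chains of the B-cell receptor) and the kinase gene Blk, from 3.06 for Blk to 4.85 for Ms4a1. Pax5 (0.82, SE 0.46, adjusted p = 0.276) and Ebf1 (0.65, SE 0.30, adjusted p = 0.192), which specify the B lineage, did not pass. Camera placed the B-cell list higher in LT-HSC with an adjusted p of 0.000255, against an adjusted p = 0.469 with an estimated correlation. Of 18 genes of early lymphoid specification, 8 were higher in LT-HSC, 1 was lower and 9 did not pass (9 and 1 adjusted over the list alone; camera adjusted p = 0.000118, adjusted p = 0.469 with an estimated correlation). Ikzf3 (Aiolos, 5.76), Blnk (an adaptor of the B-cell receptor, 4.86), Il7r (the interleukin-7 receptor, 4.58) and Bcl11b (a T-lineage factor, 2.79) led the group, and Bcl11a fell by 1.02. Without LT-HSC replicate 1 or 2, 5 or 4 members of the lymphoid list were higher, and the 4 B-cell genes passed without either. Of 7 T and NK cell markers, 4 were higher in LT-HSC, among them Cd3g (1.90) and Gzma (2.33), and Nkg7 fell by 2.63 (4 and 1 adjusted over the list alone). The list did not pass (adjusted p = 0.0572) but did without LT-HSC replicate 1 (adjusted p = 0.00692) or 2 (0.0366). Of 14 macrophage and dendritic cell markers, 5 were higher in LT-HSC, 0 were lower and 9 did not pass (5 and 1 adjusted over the list alone; camera adjusted p = 0.0461, adjusted p = 0.469 with an estimated correlation). They were Cd68 and 4 genes of antigen presentation on MHC class II (Cd74 at 3.71, H2-Aa, H2-Ab1 and H2-Eb1), which B cells also express. This last call was lost without LT-HSC replicate 1 (adjusted p = 0.0972), LT-HSC replicate 2 (0.113) or ST-HSC replicate 2 (0.145), and the list median of 0.45 became 0.20 without ST-HSC replicate 2 and 0.77 without ST-HSC replicate 3.

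Of 49 genes of G2 and mitosis, 40 fell, 0 rose and 9 did not pass (46 fell, 0 rose adjusted over the list alone), with a median log2 difference of -2.25. Top2a, the mitotic topoisomerase, was 6.07-fold lower (-2.60, SE 0.29, adjusted p = 0.00387), and Cdc20, Plk4 and Kif2c fell by 1.87, 2.52 and 1.99. A further probe set of Cdc20 was called in the opposite direction. Of 41 genes of DNA replication, 31 fell, 1 rose and 9 did not pass (32 fell and 2 rose adjusted over the list alone), with a median of -1.68. Mcm7, a subunit of the replicative helicase, was 5.08-fold lower (-2.34, SE 0.18, adjusted p = 0.00081), and Mcm6, Lig1 and Rrm1 fell by 2.19, 1.96 and 1.99. The exception was Ccne1, cyclin E1, which was 4.63-fold higher in LT-HSC (2.21, SE 0.30, adjusted p = 0.00731) and passed on 1 of its 2 tested probe sets. Of 16 G1 cyclins and kinases 7 fell, among them Cdk6 by 1.87 and Cdk4 by 1.33, while Ccne1 rose and 8 did not pass (10 fell and 3 rose adjusted over the list alone). Ect2 and Nusap1 of the mitosis list (both -3.07) stood among the 15 largest folds in ST-HSC, as did Cep55, a gene of cytokinesis outside the lists (12.2 and 54.7 in LT-HSC against 527 and 945 in ST-HSC), and Depdc1b (-3.27). Camera gave adjusted p-values of 4.81e-18 for G2 and mitosis, 3.77e-12 for replication and 0.0461 for the G1 list. Each of these had an adjusted p = 0.469 with an estimated correlation, and the G1 call was also lost without LT-HSC replicate 2 (adjusted p = 0.0628). Calls of single members rested on the LT-HSC pair: without LT-HSC replicate 1 or 2, 0 or 6 genes of G2 and mitosis, 1 or 1 of replication and 0 or 0 of the G1 list fell. The same LT-HSC arrays carried the B-cell markers, with a median of 0.82 over that list (1.87 without LT-HSC replicate 1 and 1.43 without LT-HSC replicate 2). The medians with an array left out may cover other members, since the filter was applied again. Between the LT-HSC replicates the B-cell list differed by a median of only -0.096. Within LT-HSC, replicate 1 read lower than replicate 2 over the G2 and mitosis list, by a median of -0.60.

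Of 36 genes of ribosome biogenesis 10 fell, 1 rose and 25 did not pass (13 fell and 1 rose adjusted over the list alone), with a median of -0.65 (camera adjusted p = 0.000118, adjusted p = 0.469 with an estimated correlation). The nucleolar genes Nop56, Nop58 and Fbl fell by 1.70, 2.38 and 1.72, and Odc1, ornithine decarboxylase, rose by 0.68. Without LT-HSC replicate 1 or 2 none of the members passed (0), and without ST-HSC replicate 2 or 3, 21 or 19 fell. Of 31 cytosolic ribosomal protein genes 3 fell (Rps19, Rps2 and Rpl14) and 28 did not pass (3 fell adjusted over the list alone), with a median of -0.21. That list's call (adjusted p = 0.0182, adjusted p = 0.469 with an estimated correlation) was lost without LT-HSC replicate 2 (adjusted p = 0.129), and centring the arrays on their medians turned its median to 0.02. Myc, listed with the G1 and the immediate early genes, fell by 1.85 (SE 0.31, adjusted p = 0.0155).

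Mpo, myeloperoxidase, was 35.9-fold higher in ST-HSC (-5.16, SE 0.44, adjusted p = 0.00139) and Ctsg, cathepsin G, 34.2-fold (-5.10, SE 0.75, adjusted p = 0.00974). The granule protease gene Prtn3 and the G-CSF receptor gene Csf3r fell in LT-HSC by 2.18 and 2.51. The remaining genes among the 15 largest folds in ST-HSC were Dnajc6 (-4.03), Serpinb1a (-3.35), Ccl9 (-3.35), Sh2d5 (-3.26), Tm6sf1 (-3.26), Bex6 (-3.25), Ndrg1 (-3.14) and Emilin2 (-2.91). Of 21 genes of granulocyte and monocyte progenitors 4 were higher in ST-HSC, 2 (Csf2rb and Cd68) were higher in LT-HSC and 15 did not pass (13 and 4 adjusted over the list alone), with a median of -2.18 (camera adjusted p = 0.0475, adjusted p = 0.676 with an estimated correlation). Of 14 genes of multipotent progenitors 7 were higher in ST-HSC, among them Cd34, Mpo and Cd27 (-1.93), while Cd52 (3.53) and Cd53 (1.90) were higher in LT-HSC (9 and 3 adjusted over the list alone; camera adjusted p = 0.0439, adjusted p = 0.6 with an estimated correlation). None of the 12 markers of maturing granulocytes passed singly, and camera placed that list higher in ST-HSC (median -3.69, adjusted p = 0.017, adjusted p = 0.619 with an estimated correlation). ST-HSC replicate 3 carried most of this signal, with S100a8 at 11465, against 1178 on ST-HSC replicate 2, 813 on LT-HSC replicate 1 and 18.6 on LT-HSC replicate 2. Without ST-HSC replicate 3 the granulocyte list (median -1.22, adjusted p = 0.29), the myeloid progenitor list (median -0.91, adjusted p = 0.21) and the multipotent progenitor list (adjusted p = 0.0774) no longer passed. Without ST-HSC replicate 2 the granulocyte median was -5.81 and all 12 genes passed, higher in ST-HSC, and without LT-HSC replicate 2 it was -1.61.

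**Figure D2:**
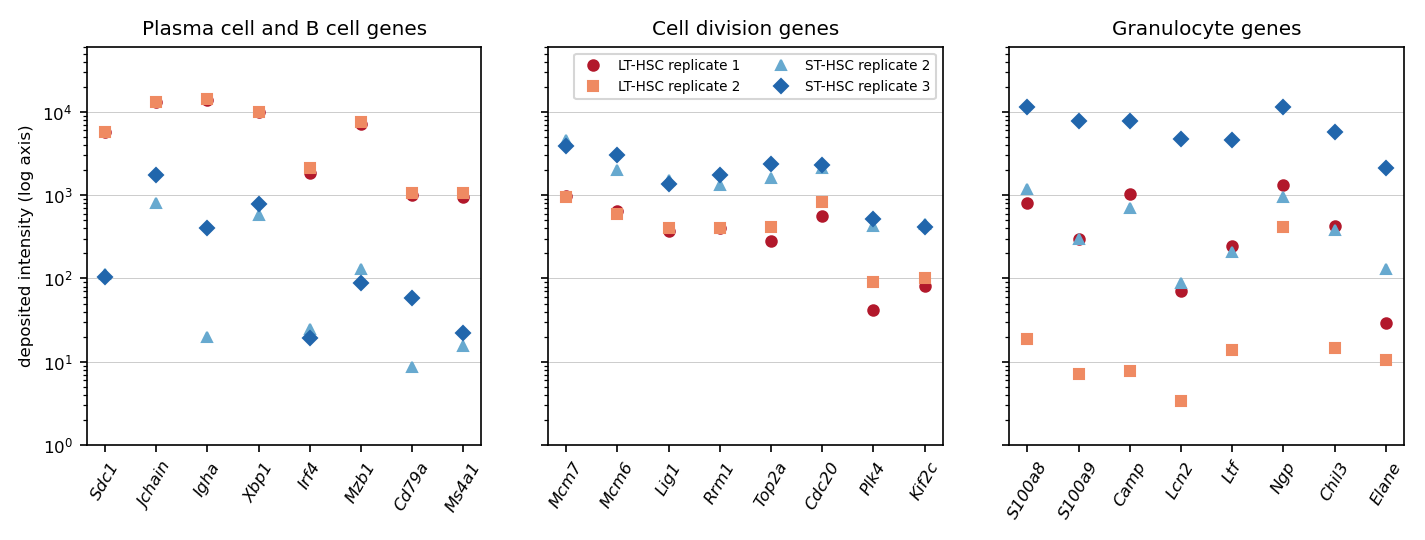
Deposited intensity on a log axis for 8 plasma and B cell genes, 8 cell division genes and 8 granulocyte genes. Each symbol is 1 array. Igha reads 13719 and 14222 on the LT-HSC arrays, Mcm7 reads 964 and 937 on the LT-HSC arrays against 4570 and 3837 on the ST-HSC arrays, and S100a8 reads 11465 on ST-HSC replicate 3.

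Of 21 tested genes of the megakaryocyte and erythroid branch 7 fell in LT-HSC, 2 rose and 12 did not pass (13 fell and 2 rose adjusted over the list alone), with a median of -1.06 (camera adjusted p = 0.00185, adjusted p = 0.469 with an estimated correlation). Nfe2 fell by 1.51, Tal1 by 1.40 and Lmo2 by 0.92, while Vwf (von Willebrand factor, 2.62, SE 0.53, adjusted p = 0.0265) and Epor (the erythropoietin receptor, 2.14, SE 0.52, adjusted p = 0.0437) rose. Of 7 erythroid markers 2 fell, Slc25a37 by 1.81 and Car2 by 1.31, and 5 did not pass (2 fell adjusted over the list alone). The erythroid list's call (adjusted p = 0.0461, adjusted p = 0.617 with an estimated correlation) was lost without ST-HSC replicate 3 (adjusted p = 0.21). Its median of -0.80 became -1.20 and -1.29 without LT-HSC replicate 1 and 2 and -1.93 without ST-HSC replicate 2. The LT-HSC replicates differed over the erythroid list by a median of only -0.012. The filter was applied again each time, so these medians may cover other members. Of 9 platelet markers Clec1b rose by 2.81 and Gp9 and Gp5 fell by 1.39 and 1.44 (1 rose and 6 fell adjusted over the list alone), and the list did not pass (adjusted p = 0.0765), but did without LT-HSC replicate 2 (adjusted p = 0.0304). Of 8 mast cell and basophil markers Mcpt8 rose by 1.55 and Ms4a2 fell by 2.29 (1 rose and 3 fell adjusted over the list alone; adjusted p = 0.0765, and 0.0187 without LT-HSC replicate 1). ST-HSC replicate 3 read above ST-HSC replicate 2 over the erythroid list by a median of 1.26. The single calls of the megakaryocyte and erythroid branch, the erythroid markers and the mast cell markers were lost without LT-HSC replicate 1 or 2.

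Immediate early genes, which respond within minutes to stimuli and to cell handling, were higher in LT-HSC. Of 30 tested 10 rose, 1 fell and 19 did not pass (12 rose and 1 fell adjusted over the list alone), with a median of 1.62 (camera adjusted p = 5.67e-05, adjusted p = 0.6 with an estimated correlation). Nr4a2 was 43.1-fold higher (5.43, SE 0.35, adjusted p = 0.000486) and Egr2 21.2-fold higher (4.40, SE 0.44, adjusted p = 0.0024), although 1 of 6 probe sets of Nr4a2 passed. Without LT-HSC replicate 1 or 2, 3 or 2 members rose, and without ST-HSC replicate 2 or 3, 24 or 17, with a list median of 2.41 or 0.70. ST-HSC replicate 3 read lower than ST-HSC replicate 2 over this list by a median of -1.50, and Fos, which did not pass, read 8944 and 9166 in LT-HSC against 5118 and 301 in ST-HSC. Of 23 restraints on the cell cycle 4 rose in LT-HSC, namely Cdkn1a (p21, 2.34), Foxo1 (2.11), Gadd45b (2.27) and Btg2 (2.59), and Rbl1 fell by 1.75 (5 rose and 2 fell adjusted over the list alone). That list did not pass in the main comparison of all 4 arrays (adjusted p = 0.0811). Its median of 0.46 became 0.62 without ST-HSC replicate 2 and 0.16 without ST-HSC replicate 3. Both its list call and its single calls depended on the array left out. The single calls were lost without LT-HSC replicate 1 or 2 and were more numerous without ST-HSC replicate 2 or 3. Of 21 genes of the BCL2 family and apoptosis 5 rose, among them the pro-apoptotic Bmf (3.43), Pmaip1 (Noxa, 3.48) and Bcl2l11 (Bim, 2.87), while Bok fell by 1.89 (9 rose and 6 fell adjusted over the list alone; list adjusted p = 0.188, and 0.0496 without ST-HSC replicate 3). Of 28 genes of Polycomb, Trithorax and DNA methylation, Bmi1, a Polycomb gene required for stem cell self-renewal, rose by 2.61 (SE 0.29, adjusted p = 0.00367) on 1 of its 2 probe sets. Cbx7 rose by 1.56, and Dnmt1, Ezh2, Cbx2 and Hdac2 fell by 1.61, 1.69, 1.25 and 1.54 (2 rose and 6 fell adjusted over the list alone; list adjusted p = 0.622). The single calls of this list, Bmi1 among them, were also lost without LT-HSC replicate 1 or 2.

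Of 28 tested genes commonly associated with LT-HSC 1 rose (Vwf), 2 fell (Angpt1 by 1.30 and Gfi1b by 1.61) and 25 did not pass (2 rose and 2 fell adjusted over the list alone), with a median of -0.10, a mean of 0.01 and an adjusted p of 0.93. Hlf (-0.44, SE 0.34), Mecom (-0.43, SE 0.39) and Procr (0.52, SE 0.46) did not pass, with Hlf at 1116 and 786 in LT-HSC against 1495 and 896 in ST-HSC. Without ST-HSC replicate 3 the gene Hlf (-0.90, adjusted p = 0.00208) and Mecom (-0.98, adjusted p = 0.00234) passed as lower in LT-HSC, and without ST-HSC replicate 2 Procr passed as higher (1.29, adjusted p = 0.000153). Few members passed in the signalling lists: Smad1 fell by 1.38, Tgfb1 fell by 2.22 and Skil rose by 1.57 of 29 TGF-beta and BMP genes (median -0.30), Fzd7 fell by 1.26 of 23 Wnt genes (median -0.10), and Nrarp fell by 1.23 of 22 Notch genes (median 0.08). Adjusted over the list alone, 1 rose and 2 fell in the TGF-beta list and 0 passed in the Wnt and Notch lists. The list p-values were 0.373, 0.93 and 0.917, and camera placed the Wnt list higher in LT-HSC against the sign of its median. Of 20 Hox and TALE genes Hoxa9 and Hoxa10 fell by 1.76 and 1.48 (4 fell adjusted over the list alone; median -0.18, list adjusted p = 0.334). Of 32 interferon-stimulated genes Ifit2 and Oas1a fell by 1.76 and 1.35 (1 fell adjusted over the list alone), with a median of 0.10, a mean of -0.04 and a list adjusted p of 0.991. Of 33 genes of adhesion and the niche 5 rose, among them Cdh2 (N-cadherin, 3.26) and Itgal (2.52), and Kit fell (9 rose and 4 fell adjusted over the list alone; list adjusted p = 0.214). Of 12 stromal and endothelial markers Stab2 rose by 3.53 (1 adjusted over the list alone; median -0.04, mean 0.20, list adjusted p = 0.592), and of 13 imprinted growth genes Igf2r was 2.82-fold higher (1 adjusted over the list alone; list adjusted p = 0.274). Most of these single calls were lost without LT-HSC replicate 1 or 2.

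In energy metabolism and antioxidant defence single genes passed, and all of these calls were lost without LT-HSC replicate 1 or 2. Of 25 genes of glycolysis and the hypoxia response 4 fell (Ndrg1, Ldha by 0.74, Hk1 by 1.03 and Pkm by 1.09), Pfkp rose by 1.66 and 20 did not pass (8 fell and 1 rose adjusted over the list alone). Of 50 genes of oxidative phosphorylation Ndufa1 alone passed, 1.40 higher in LT-HSC (1 adjusted over the list alone). Of 31 antioxidant genes Prdx4 rose by 1.65 and Gpx1, Txnrd1 and Nqo1 fell by 1.08, 1.35 and 1.48 (2 rose and 3 fell adjusted over the list alone). None of these 3 lists passed in the main comparison of all 4 arrays, with adjusted p-values of 0.0765, 0.104 and 0.104. The glycolysis list lay at a median of -0.43, at -0.60 without ST-HSC replicate 2 and at -0.40 without ST-HSC replicate 3. The oxidative phosphorylation list lay at a median of -0.31, at -0.52 without ST-HSC replicate 2 and at -0.046 without ST-HSC replicate 3. With the arrays centred on their medians its median was 0.026. Whether the glycolysis and oxidative phosphorylation lists passed depended on the array left out. In all 15 of the 33 lists passed in camera, 0 passed with an estimated correlation, where the smallest adjusted p was 0.469, and 0 passed in fry, where the smallest was 0.0511. With no filter on dim probe sets 6 more lists passed, those of T and NK cells (adjusted p = 0.0204), cell cycle restraints (0.0322), glycolysis (0.0307), mast cells (0.0322), platelets (0.0322) and oxidative phosphorylation (0.0427). Median centring added T and NK cells (0.0488) and mast cells (0.0365), averaged probe sets T and NK cells (0.0236) and apoptosis (0.0269), a pseudocount of 1 T and NK cells (0.0444), and the stricter filter apoptosis (0.0347). Calls were lost under the stricter filter for the G1 (0.0792), multipotent (0.062), myeloid (0.0792) and erythroid (0.0741) lists, with averaged probe sets for the G1 (0.0702), multipotent (0.0702) and macrophage (0.0576) lists, and at a pseudocount of 64 for the G1 (0.0512) and myeloid (0.076) lists. The macrophage list was also lost with median centring (0.0597) and with no filter (0.0931), the G1 list as deposited (0.0529), and the ribosomal protein list as deposited (0.54) and with median centring (0.903).

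**Figure D3:**
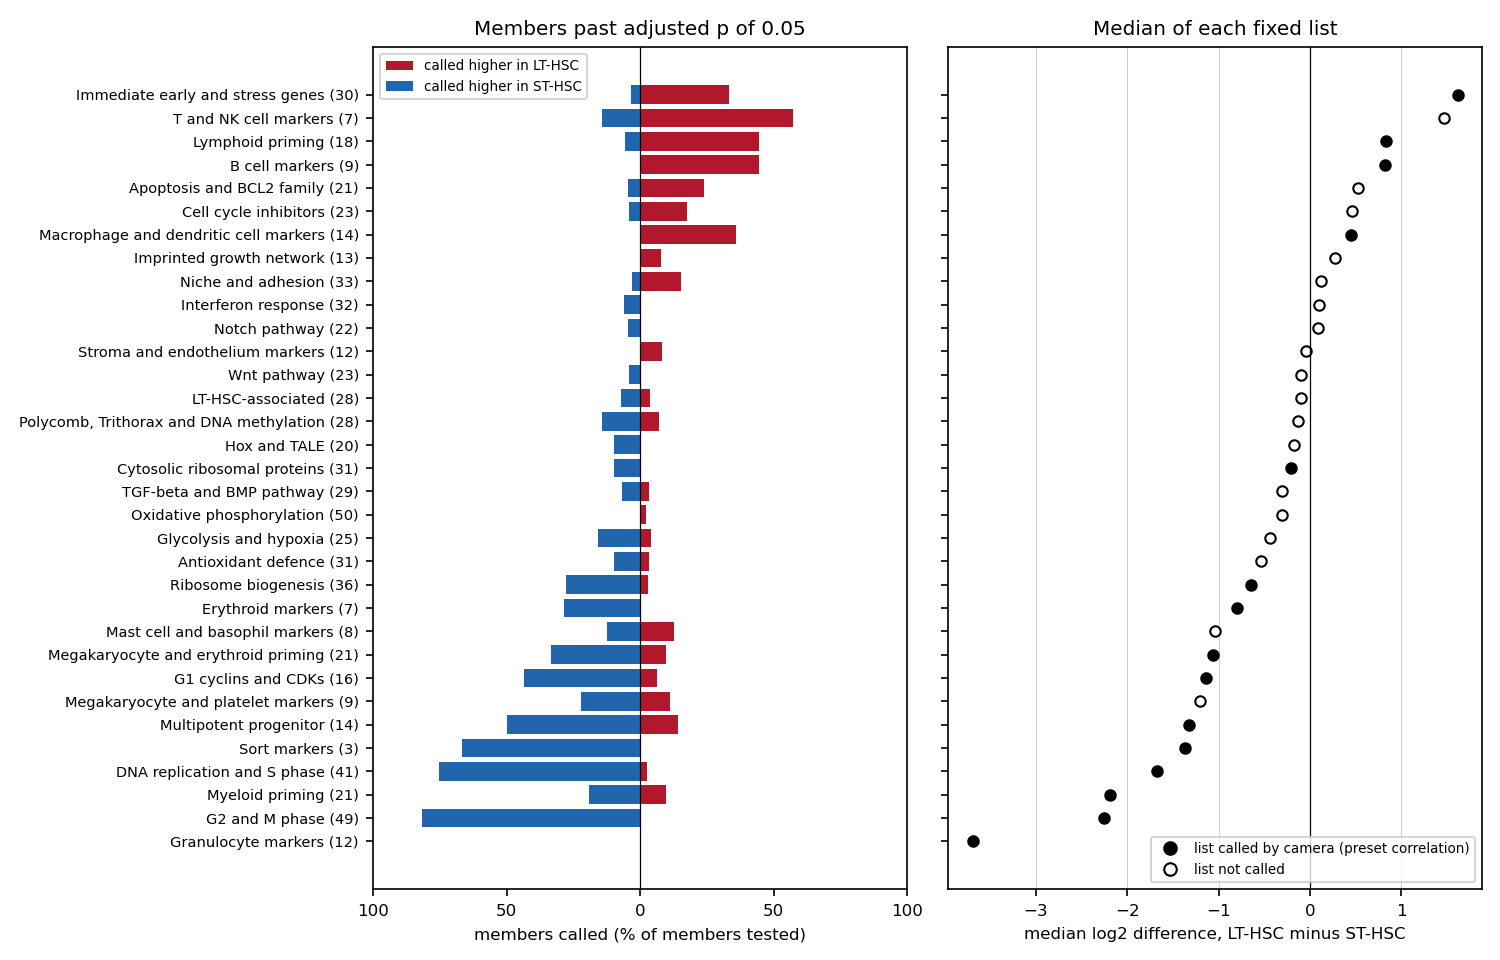
The 33 fixed gene lists, with the number of tested members in parentheses. Bars give the percentage of members past an adjusted p of 0.05 in each direction, and points the median log2 difference, LT-HSC minus ST-HSC, filled where camera at the preset correlation called the list. G2 and mitosis has a median of -2.25 and the immediate early genes 1.62.

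ST-HSC replicate 3 stood apart in technical readings. Its ratios of 3′ to 5′ intensity were 6.65 for beta-actin and 6.59 for Gapdh, against 18.4 to 19.6 and 13.9 to 15.7 on the other 3 arrays, and its log2 ratio for beta-actin differed from their mean by -1.49. A probe set of Xist, the transcript of the inactive X chromosome, read 2424 on ST-HSC replicate 3 and at most 34.1 on the others, and the Y-linked gene Eif2s3y read 6.19 there and 276 to 333 on the others. The LT-HSC arrays differed from each other with an SD of 0.49 on the log2 scale over the tested probe sets, with 1404 probe sets over 2-fold apart, and the ST-HSC arrays with an SD of 0.70 and 3387 probe sets. The first principal component held 74.0% of the variance and separated LT-HSC from ST-HSC, and the second held 16.9% and separated the ST-HSC arrays. Without ST-HSC replicate 3, 1 of the 1823 called genes that were still tested changed direction. This cannot show that the replicate is harmless, because all 1837 called genes had both arrays of 1 group above both of the other.

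**Figure D4:**
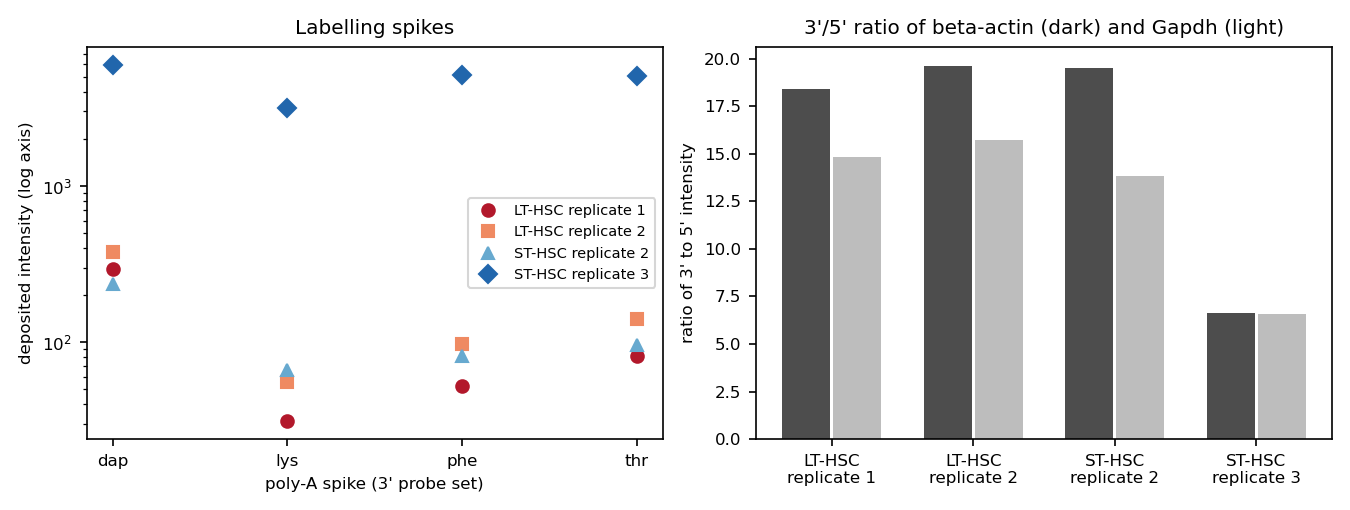
Left, deposited intensity on a log axis of the 3′ probe sets of 4 poly-A labelling spikes on each array. Right, ratio of 3′ to 5′ intensity of beta-actin and Gapdh on each array, where ST-HSC replicate 3 reads 6.65 and 6.59 and the other arrays lie at 13.9 or above.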

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

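The tests weighed here were chosen after the results were seen, except that the G2 and mitosis median without ST-HSC replicate 3 was chosen beforehand as a way to check every list. The poly-A spikes, bacterial transcripts that are added before labelling and are outside the gene comparison, read brightly on ST-HSC replicate 3 alone: dap 5950, lys 3162, phe 5147 and thr 5014, against at most 379, 66.6, 96.8 and 140 on the other 3 arrays. A labelling kit with spikes for that array is not recorded in the labels, and ST-HSC replicate 3 also held the only female-type reading of Xist (2424).

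Genes of plasma and B cells were higher in LT-HSC. Quantile normalization as the cause is argued against by the deposited values, where 31 tested plasma cell genes had a median log2 difference of 4.14. Any scaling before deposit is unknown and was not tested. Single misread probe sets are argued against by the further probe sets of 17 of the 35 called plasma and B cell genes. Of these probe sets 20 of 23 (87.0%) were higher in LT-HSC, against 75.5% of 828 for all genes called higher there. Misreading stays open for the 18 genes without a further probe set. Plasma cell RNA in both LT-HSC samples is a candidate explanation and stays open: 31 of the 31 genes (100%) were called higher, Jchain at 13176 and 13056 and Igha at 13719 and 14222 were near the top of the arrays, whose highest readings were 15241 and 15893, and its secretory pathway genes, such as Edem1 (4.83) and Hsp90b1 (2.14), were among those called (list adjusted p = 0.0327 with an estimated correlation, over the 3 later lists). The list was made after the data were seen, so its count and p-value restate the pattern and are no separate test of this explanation. That p-value was also adjusted over fewer lists than those of the fixed lists and cannot be compared with them. Of the list's genes 3 are among the 15 largest folds, 0 are in a fixed list and 16 read above 64 on both ST-HSC arrays. The lineage-negative and cKit+ gates would be expected to remove such cells. A true difference between CD34- and CD34+ stem cells, or another response to poly(I:C), was not tested.

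Cell division genes were lower in LT-HSC. ST-HSC replicate 3 alone is argued against by a median of -1.87 over the G2 and mitosis genes without it. Quantile normalization is argued against by a median of -2.31 in the values as deposited. Dilution of stem cell RNA by other cells was weighed with 23 genes shared by stem and progenitor cells, whose median was -0.92. The G2 and mitosis median lay below theirs by a difference of -1.33 (95% bootstrap interval over genes -1.70 to -0.96). That difference shrank to -0.60 (-0.98 to -0.42) without ST-HSC replicate 3 and to -0.80 (-1.34 to -0.50) without LT-HSC replicate 1. It cannot decide whether dilution is the whole cause, because other cells that express some of the shared genes would hold their median up. The interval also treats genes as independent. Those shared genes were themselves lower in LT-HSC (9 of 23 called, 0 higher; adjusted p = 0.232 with an estimated correlation; 19 called and a median of -1.27 without ST-HSC replicate 3, 0 called without either LT-HSC replicate, and 11 lower and 1 higher without ST-HSC replicate 2), among them Sox4 (-2.82) and Myb (-1.60), so dilution may account for part of the pattern. A biological difference between these stages, which the design names, stays open and was not tested, and genes that fall for other reasons within the shared list keep the size of the dilution unknown.

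Granulocyte genes were bright on ST-HSC replicate 3. A shift common to genes of like level on that array is argued against by the list's median of 3.83 over ST-HSC replicate 2. That median stood at percentile 100 of 10000 random lists of like level, whose highest median was 0.82. Effects of amplification or RNA integrity that differ between transcripts stay open, because the random lists were matched on level alone. The percentile also restates the pattern, since the list was picked out for its brightness on ST-HSC replicate 3. Granulocyte RNA in that sample stays open, since no test of it was run apart from the pattern itself (12 of 12 tested markers, 100%, over 2-fold brighter, with S100a8 at 11465, Ngp at 11425 and Camp at 7687), a lineage gate is meant to remove such cells and 1 member (Elane) is also in the myeloid progenitor list. LT-HSC replicate 1 also read above LT-HSC replicate 2 over this list, by a median of 2.38 (percentile 100), in a pair of the same age and interval. Sex, age and time since injection cannot be told apart from the sample itself, because 1 array alone has that age and interval, and no biological explanation was tested.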

How the results depend on the processing

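Of the alternatives, the values without normalization between arrays were chosen after the data were seen. The 3293 probe sets, 1814 higher in LT-HSC and 1479 in ST-HSC, and the 1837 genes moved by over 1.5 times at an adjusted p under 0.10, to 5747, 2748, 2999 and 3070, since a looser threshold admits more. They also moved with each array left out, where the group left with 1 array is assumed to vary like the other: probe sets 416 to 8775, LT-HSC 400 to 4249, ST-HSC 13 to 4526, genes 249 to 4801. Without an LT-HSC array the spread came from the wider ST-HSC pair, and without an ST-HSC array from the closer LT-HSC pair. Under the other normalizations, filters, pseudocounts, spread models and probe set rules the gene count stayed between 1431 and 2471. The 15 lists became 0 with an estimated correlation and 0 in fry; 13 to 17 passed with each array left out. Cd34 passed under every setting. Kit lost its call as deposited (-0.99), with median centring (-0.88), without the filter, without trend and with robust trend (-1.02 each), at pseudocounts 1 (-1.05) and 64 (-0.94), with mean probe sets (-0.49) and without either LT-HSC array, and lay from -1.24 to -0.85 with arrays left out. Flt3 gained one with median centring (-1.35), at adjusted p under 0.10 and with mean probe sets (-1.37 each) and without ST-HSC replicate 3, and lay from -1.74 to -0.99 with arrays left out. The beta-actin difference of -1.49 became -1.40 at pseudocount 64. Turned in sign, with none past the threshold: oxidative phosphorylation -0.078 as deposited and 0.026 centred; LT-HSC-associated genes -0.098 unfiltered; interferon response 0.096 unfiltered, 0.092 at pseudocount 64 and 0.029 with mean probe sets; Meg3 0.018 with mean probe sets. For lists the direction is that of camera, the value the median. With arrays left out the turned results ranged from lowest to highest as follows: LT-HSC-associated -0.38 to 0.24, interferon -0.082 to 0.12, Wnt -0.19 to 0.16, Notch 0.0068 to 0.17, TGF-beta -0.48 to -0.053, chromatin -0.31 to -0.078, stroma -0.24 to 0.28, Mecom -0.98 to 0.11, Procr -0.21 to 1.29 and Xist -5.84 to 0.35. The Xist difference rested on ST-HSC replicate 3, where its brightest probe set read 2731, against at most 70.9 on the others. For the other turned results the cause was not tested. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Dim probe sets limit all of this: those near the pseudocount have folds set by it.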

Other observations

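Genes of innate lymphoid and T-lineage cells, in a list made after the data were seen, were also higher in LT-HSC: 12 of 21 tested were called, 0 were lower and 9 did not pass, with a median log2 difference of 1.72 (adjusted p = 0.0327 with an estimated correlation, over the 3 later lists). Because of that later choice, the list's p-value is no separate test, and it cannot be compared with those of the fixed lists. Cxcr6, a chemokine receptor of tissue lymphocytes, read 481 and 414 in LT-HSC and 0.483 and 0.311 in ST-HSC. Icos (3.99), Cd28 (3.98) and Gata3 (1.67) rose with it, and Il7r is shared with the fixed lymphoid list, as are 4 others with fixed lists. Chosen after its values were seen, Ly6d, a surface marker of early B-lineage cells, was 26.1-fold higher in LT-HSC (4.71, SE 0.29, adjusted p = 0.00042). Ighm, the heavy chain of IgM, likewise chosen, did not pass on its brightest probe set, at 9121 and 10172 in LT-HSC and 8373 and 7448 in ST-HSC, but 7 of its 8 tested probe sets were called higher in LT-HSC.

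Among called genes with further tested probe sets, 75.5% of 828 such probe sets lay in the same direction for genes higher in LT-HSC and 85.8% of 668 for genes higher in ST-HSC. Of those probe sets 29.6% and 33.2% were themselves called in that direction. Igk, also chosen after its values were seen, is 1 of 10 called genes with opposing probe sets: its brightest probe set fell by 1.57 in LT-HSC, and 2 others were called higher there.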
